A study of Arabidopsis thaliana with 19 samples.

How the data were processed

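Transcript levels in shoots of Arabidopsis thaliana seedlings had been measured on 19 Affymetrix ATH1 arrays, 1 array per sample. The deposited values are linear MAS5 signal values, a probe set intensity with a positive number for every probe set, and replicates were not pooled. Per the submitters' processing notes the arrays were summarised with MAS5, and no version was given. The authors scaled each array, as the deposited values themselves show, so that the mean signal left after removing 2% of the values at each end is 250. Because of that scaling only relative levels can be compared. Direction and scale are thus known, and the values show no centring of genes. The notes mention neither detection calls nor the dates of labelling or scanning, so batches within an experiment could not be tested.

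Arrays were grouped by their titles into 9 groups in 3 experiments, each with its own wild type arrays. The names used for the groups are MYB29_OE, MYB76_OE, ATR1_OE and MYB51_OE for seedlings overexpressing that factor, and ATR1_like_miR and MYB28_like_miR for seedlings whose labels name an artificial microRNA together with that factor and the word like. The wild type groups are WT_MYB29_MYB76, WT_ATR1_MYB51 and WT_miR. For 1 array, MYB28_like_miR replicate 2, the source field names another construct than the title, and the title was followed. The labels do not say whether replicates were grown separately, so the p-values measure the spread between these arrays, which may be technical in part.

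Each array's 20th percentile was used as a floor: lower values were raised to it before log2 was taken. A change against a group whose arrays all lie at the floor is a lower bound and is printed as "at least", as are the rises of AT2G25450 and AT3G05400 over wild type arrays of which 2 of 3 lie there. Changes of other genes with 1 array of a group at the floor, among them MSRB5, BGLU28 in ATR1_OE and MYB51_OE, rps3 and rps19, depend on the floor in part. Probe sets were tested if their signal reached the array's 40th percentile on at least 2 arrays, and the 64 control probe sets of the array were left out, which left 15627 of 22810 probe sets. One linear model with a mean for each of the 9 groups was fitted to all 19 arrays with limma 3.58.1 (lmFit, eBayes with trend) in R 4.3.3, which gave 10 residual degrees of freedom and 5.62 prior degrees of freedom. Every group thus shares one estimate of the spread per probe set. The 6 comparisons with wild type and the 3 comparisons between lines of an experiment are contrasts of this model. Adjusted p-values are from Benjamini and Hochberg's method over all probe sets tested, and a probe set was called changed when its adjusted p was under 0.05. All tests were two-sided. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15. Replicate numbers were used as a block only in an alternative.

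Probe sets were named through the array annotation table and a table of RefSeq genes of the assembly TAIR10.1. Of all probe sets 13513 were assigned to 1 gene, 503 to several genes and 8794 were not listed. Of those tested, 8577 had 1 gene (8453 genes), 311 had several and 6739 were not listed. A probe set without a listed gene is unnamed here, and may still measure a known gene. The probe sets for MYB29, MYB76, ATR1, MYB51, MYB28 and their relatives are among the unnamed ones. Whether the introduced genes were overexpressed or the targeted genes reduced could therefore not be read from these tables.

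Gene lists were tested with camera, which compares the changes of a list with those of all other probe sets, with a preset correlation of 0.01 between genes, and again with an estimated correlation. Lists with at least 3 measured members were tested, and their p-values were adjusted within a comparison, apart for lists fixed earlier and lists added later. Fixed before the data were examined were the groups, the model, the rule for naming genes and 24 lists with 295 genes. Only 42 of these genes were named on the array and 38 were measured, so 7 of the lists were tested: aliphatic glucosinolate synthesis, glucosinolate breakdown and transport, sulfate assimilation, methionine, auxin biosynthesis, auxin response and flavonoids. For these the count of changed genes was also adjusted over the list alone. Added after seeing the annotation were 19 lists, 18 of them tested: plastid-encoded genes, nuclear genes of photosynthesis, heat shock, ER body, cold response, cell division, touch and wounding, and 11 gene families. The rule for naming genes took, in each comparison, the measured genes of glucosinolate synthesis, the 5 largest rises and 5 largest falls among changed probe sets of 1 gene whose arrays did not overlap and whose means lay above the floor (read as at least 1 array of each group above its own floor), and up to 4 changed members of any other list. Probe sets given by their identifier alone, and genes shared between lines, were chosen after their values were seen.

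The models were tested on simulated data with the spread of the real arrays and 200 changed probe sets. At a fold change of 4 the share recovered was 86.4% of the changed probe sets for MYB29_OE (15011 probe sets), 89.4% for MYB76_OE (15034), 84.8% for ATR1_OE (15031), 93.9% for MYB51_OE (15032), 80.3% for ATR1_like_miR (15026) and 80.3% for MYB28_like_miR (15020). At a fold change of 2 the shares were 19.4%, 29.9%, 26.9%, 22.4%, 13.4% and 22.4%, in the same order. Between 1 and 5 unchanged probe sets were called, and none in the wrong direction. Each simulated value varied independently of the others, without differences shared by an array or an experiment. The simulation therefore cannot show how many calls such differences give on the real arrays. The shares recovered hold for 200 changed probe sets and for this independent noise.

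Alternatives fixed with the design were quantile normalization, no floor, the 20th percentile added as an offset, no filter, a filter at the 60th percentile, a model of each experiment alone, all 7 wild type arrays as the control, eBayes without the trend, the replicate number as a block, each array left out in turn, a threshold of 2-fold as well, and the estimated correlation. Chosen after seeing the data were the omission of plastid-encoded probe sets, the wild type arrays of the other 2 experiments as the control, each array's median plastid-encoded signal as a covariate, a crossed replicate block and the wild type arrays split between the lines that share them. For pairs of comparisons with the same control, unchanged groups were simulated against shared controls 50 times. The number of arrays limits the precision, and low signals near the floor limit the size of the changes that can be measured.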

Results

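Transcript levels were measured in 14-day-old Arabidopsis thaliana seedlings, without cotyledons and hypocotyls, that overexpressed 1 of 4 MYB transcription factors or carried 1 of 2 artificial microRNAs. The plants had grown at 20 °C with 10 h of light and 14 h of darkness, and 15 µg of total RNA were used per array. MYB28, MYB29 and MYB76 are known as regulators of aliphatic glucosinolates, sulfur-containing defence compounds made from methionine, and ATR1 and MYB51 as regulators of indole glucosinolates, made from tryptophan. An artificial microRNA is a designed small RNA that lowers chosen transcripts. The first experiment held MYB29_OE (2 arrays), MYB76_OE (2) and wild type (WT_MYB29_MYB76, 3). The second held ATR1_OE (2), MYB51_OE (2) and wild type (WT_ATR1_MYB51, 2), and the artificial microRNA experiment held ATR1_like_miR (2), MYB28_like_miR (2) and wild type (WT_miR, 2). Median signal per array lay between 78.4 and 106 and the floor between 12.4 and 19.1. Log2 signals of replicates correlated across probe sets with r from 0.911 to 0.986. The number of arrays limits the precision of every comparison. Probe sets of the 6 regulators themselves could not be named, so their own levels are not given.

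In MYB29_OE, compared with wild type to ask which transcripts differ when MYB29 is overexpressed, genes of aliphatic glucosinolate synthesis rose together. All 5 measured genes of the 26-gene list rose, with a mean log2 change of 2.80. AOP3 (AT4G03050), a dioxygenase of side chain modification, rose 10.3-fold, from 918.9 ± 318 (SD, n = 3) to 9103 ± 1520 (SD, n = 2). BCAT4 (AT3G19710), the aminotransferase that begins methionine chain elongation, rose 5.87-fold to a signal of 8249 ± 1688 (SD, n = 2). AT2G25450, known as GSL-OH, rose at least 17.8-fold to 273.4 ± 32.3 (SD, n = 2) from 11.5 ± 9.13 (SD, n = 3), a level at the floor on 2 of 3 arrays. The glucosyltransferase UGT74C1 (AT2G31790) rose 4.38-fold and the glutathione transferase GSTU20 (AT1G78370) 3.55-fold. UGT74B1 (AT1G24100), a glucosyltransferase of the core pathway, rose by 1.62 ± 0.36 (SE) on the log2 scale, with a limma adjusted p = 0.00948. The list passed camera's test (adjusted p = 6e-07; adjusted p = 0.0274 with an estimated correlation), and 5 of its genes were called adjusted over the list alone.

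Of the sulfur genes, 4 also rose in MYB29_OE, while the beta-glucosidase gene PYK10 and 3 genes of the auxin response fell. The ATP sulfurylase APS3 (AT4G14680) rose 11.2-fold, from 233.1 ± 45.1 (SD, n = 3) to 2623 ± 648 (SD, n = 2), and the sulfite reductase SIR (AT5G04590) 1.74-fold. Cystathionine beta-lyase CBL (AT3G57050) rose 3.21-fold and methionine gamma-lyase MGL (AT1G64660) 2.31-fold. The sulfate assimilation list (2 of 3 rose; adjusted over the list alone, 2 rose and 1 fell) and the methionine list (2 of 3 rose; adjusted over the list alone, 2) missed camera's threshold at adjusted p = 0.0608 and 0.0554. PYK10 (AT3G09260), which acts in the ER body, fell 3.78-fold, the 1 called gene of 3 in the breakdown and transport list (1 adjusted over the list alone), whose mean of -1.05 passed camera at adjusted p = 0.038 but not with an estimated correlation (adjusted p = 0.0832), nor without wild type replicate 1 or 2 or MYB29_OE replicate 2. In the auxin response list 3 of 5 genes fell (3 adjusted over the list alone): IAA29 at least 6.43-fold to the floor, HAT2 by 1.72 and the auxin-conjugating enzyme GH3.5 (WES1) by 1.39 on the log2 scale. That list's mean of -1.22 gave a camera adjusted p = 0.0052, and adjusted p = 0.0832 with an estimated correlation, and both lists missed the threshold with the plastid-encoded signal as a covariate (means of -0.25 and -0.48; adjusted p = 0.77 and 0.323). That signal differs between MYB29_OE and its wild type almost as the groups do, so the fit with the covariate can hardly separate signal and line. Single called members of other lists were IGPS (AT2G04400), a synthase of the tryptophan pathway (log2 0.68), the transcription factor MYC3 (log2 -0.75), the phenylpropanoid enzyme HCT (log2 -0.62), and the leaf polarity genes YAB3 (log2 0.97) and PHV (log2 0.93).

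Outside the lists, the highest rise of a named gene was that of BGLU28 (AT2G44460), a beta-glucosidase of the myrosinase type, from 21.6 ± 2.35 (SD, n = 3) to 1295 ± 247 (SD, n = 2), or 5.90 ± 0.30 (SE) on the log2 scale (limma adjusted p = 2.3e-08). AT3G05400 rose by at least 4.65 ± 0.43 (SE) and MSRB5 (AT4G04830), a methionine sulfoxide reductase, by 4.43 ± 0.49 (SE). Among named genes not at the floor on every array of a group, the 5 deepest falls were plastid-encoded: rps3 fell by 6.83, rps19 by 6.79, atpE by 6.53, rpl22 by 6.48 and psbM by 6.44. Of 68 plastid-encoded probe sets, 58 fell, but with the wild type arrays of the other experiments as the control the mean of the list was -0.28 (camera adjusted p = 0.347) in place of -4.26. The median plastid-encoded signal was 5.26 ± 0.24 (SD, n = 2) on the log2 scale in MYB29_OE and 9.73 ± 1.64 (SD, n = 3) in its wild type. Among nuclear genes AT1G67870 fell by 4.07 ± 0.64 (SE), and MSRB6 (AT4G04840) and AT2G05540 each fell by 3.33. In all, limma called 2301 of 15627 probe sets, 1265 higher and 1036 lower. Arrays of the groups did not overlap for 2290 of them, and 1279 changed at least 2-fold (588 higher, 691 lower). Left-out arrays moved that count to 288 (without MYB29_OE replicate 2), 1239 (without MYB29_OE replicate 1) and 1528 (without WT_MYB29_MYB76 replicate 1), and it was 217 with all 7 wild type arrays as the control. BCAT4, IGPS, MGL, MYC3 and HCT lost their calls without either MYB29_OE array or without wild type replicate 1 or 3, GH3.5 without MYB29_OE replicate 2 or wild type replicate 1 or 3, SIR and YAB3 without MYB29_OE replicate 2 or wild type replicate 1, and GSTU20, UGT74B1, PYK10, HAT2, PHV and MSRB6 without MYB29_OE replicate 2.

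In MYB76_OE the same comparison was made for MYB76, and all 5 measured aliphatic glucosinolate genes rose here too, by a mean of 2.80 on the log2 scale. AOP3 rose 10.5-fold to 9233 ± 91.1 (SD, n = 2) and AT2G25450 at least 24.6-fold to 377.9 ± 14 (SD, n = 2). BCAT4 rose 5.12-fold to 7124 ± 10.3 (SD, n = 2), AT2G31790 3.82-fold and GSTU20 3.3-fold. UGT74B1 rose 2.49-fold. The list gave a camera adjusted p = 4.59e-07 and adjusted p = 0.026 with an estimated correlation, and 5 genes were called adjusted over the list alone.

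Of the sulfur genes, APS3 rose 10.4-fold and CBL 3.57-fold in MYB76_OE. The methionine list (1 of 3 rose; adjusted over the list alone, 2) had a mean of 1.05 and a camera adjusted p = 0.0451, which was 0.108 as the adjusted p with an estimated correlation, and was over the threshold too without wild type replicate 1 or 2, with the 60th percentile filter (0.0664), without the trend (0.0593) and with the plastid-encoded signal as a covariate (0.157). The sulfate assimilation list (1 of 3 rose; adjusted over the list alone, 2) gave adjusted p = 0.0847. None of the 5 auxin response genes was called in MYB76_OE, nor was any of the 3 genes of glucosinolate breakdown and transport. MYC4 (log2 -1.38), HCT (log2 -0.57), PHV (log2 0.96) and YAB3 (log2 0.83) were called.

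BGLU28 rose most among named genes, to 1915 ± 48 (SD, n = 2), or 6.48 ± 0.30 (SE) on the log2 scale (limma adjusted p = 6.81e-09). AT3G05400 (at least 5.51 ± 0.43, SE), MSRB5 (4.66 ± 0.49, SE) and AT5G48570, a peptidyl-prolyl isomerase of the FKBP type that rose 14.7-fold, were among the other large rises. Plastid-encoded transcripts led the falls: rps3 fell by 7.30, rps19 by 7.28 and rps4 by 7.09, and 54 of 68 such probe sets fell, with a list mean of -4.32 that became -0.35 (camera adjusted p = 0.184) against the wild type arrays of the other experiments. Their median signal was 5.11 ± 0.17 (SD, n = 2) on the log2 scale. Among nuclear genes MSRB6 fell by 3.88 and AT2G47880 by 3.57. Altogether 1994 probe sets were called by limma, 1118 higher and 876 lower, and 1146 of them changed at least 2-fold (567 higher, 579 lower). The count was 386 without MYB76_OE replicate 1, 472 without replicate 2 and 253 with all 7 wild type arrays as the control. BCAT4, GSTU20, UGT74B1, HCT, PHV and YAB3 lost their calls when either MYB76_OE array was left out, all of these but GSTU20 and PHV also without wild type replicate 1 or 3 (YAB3 without any), MYC4 without MYB76_OE replicate 1 or wild type replicate 1, and MSRB6 without MYB76_OE replicate 2.

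MYB29_OE and MYB76_OE were compared directly to ask where these lines differ. Only 4 probe sets were called by limma, 1 higher and 3 lower in MYB29_OE (2 higher and 3 lower with quantile normalization), against 513 at an unadjusted p under 0.05. None of the 4 is named. The 1 that was higher, 250598_at, had a signal of 1780 ± 247 (SD, n = 2) in MYB29_OE and 116 ± 17.9 (SD, n = 2) in MYB76_OE. Of those lower, 250589_at differed by -3.00 on the log2 scale and 266142_at lay at the floor in MYB29_OE. The former lost its call without any array but MYB29_OE replicate 1, and the latter without any 1 of the 4, while the count was 1 without MYB76_OE replicate 1 and 21 without MYB29_OE replicate 1. The aliphatic list did not pass the test, with a mean difference of 0.00 (camera adjusted p = 0.806) and of -0.01 with quantile normalization. The auxin response list was lower in MYB29_OE by a mean of 0.87, a log2 difference of -0.87 with a camera adjusted p = 2.73e-05 (0.0321 as the adjusted p with an estimated correlation), and 2 genes were called adjusted over the list alone. The breakdown and transport list differed by -0.76 (camera adjusted p = 0.00503; adjusted p = 0.0321 with an estimated correlation; mean -0.43 and over the threshold without MYB29_OE replicate 2), with 1 gene called adjusted over the list alone.

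Against the wild type arrays that both lines share, 819 probe sets other than plastid-encoded ones rose and 526 fell in both. Independent lists of these sizes would share 90.9 and 51.7, a baseline that does not allow for the shared wild type arrays. The log2 changes correlated across probe sets with r = 0.865 (0.4 in simulated unchanged groups) and a covariance of 0.412 (0.041 simulated). Probe sets are not independent replicates. With the 3 wild type arrays split between the lines, r lay between 0.494 and 0.705 over the 6 ways, and from 196 to 335 probe sets rose and 134 to 239 fell in both.

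**Figure D1:**
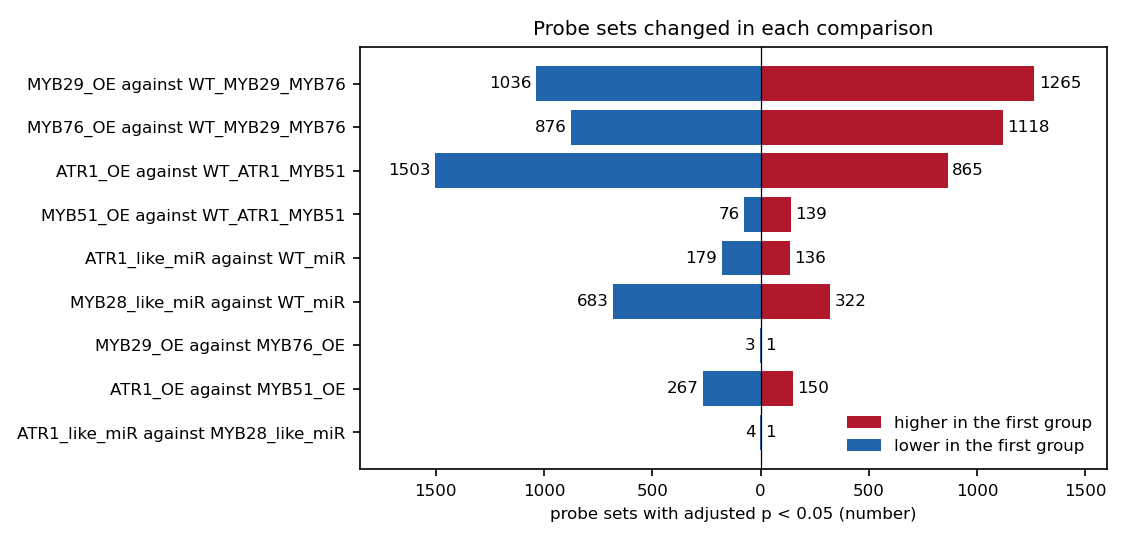
Probe sets called higher and lower (bars, number of probe sets, axis from 0) in each of the 9 comparisons. ATR1_OE had the most calls, 2368, and the direct comparison of MYB29_OE with MYB76_OE the fewest, 4.

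ATR1_OE was compared with its wild type to ask which transcripts differ when ATR1 is overexpressed, and IGPS of tryptophan synthesis, UGT74B1 of core glucosinolate synthesis and genes of sulfur metabolism rose. IGPS, the 1 measured gene of the tryptophan list, rose 7.57-fold, from 762.1 ± 50.5 (SD, n = 2) to 5826 ± 1243 (SD, n = 2; limma adjusted p = 3.67e-06). UGT74B1 rose 7.98-fold, from 349.5 ± 210 (SD, n = 2) to 2526 ± 138 (SD, n = 2). APS3 rose 22.8-fold and SIR 2.59-fold. The sulfate assimilation list (2 of 3 rose; adjusted over the list alone, 2) had a mean of 1.95 and a camera adjusted p = 0.00119 (adjusted p = 0.0329 with an estimated correlation). MGL rose 3.02-fold and CBL 2.29-fold, and the methionine list (2 of 3 rose; adjusted over the list alone, 2) gave a camera adjusted p = 0.0111 (adjusted p = 0.0412 with an estimated correlation).

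In the auxin response list, 4 of 5 genes rose in ATR1_OE. The auxin-conjugating enzymes GH3.3 (AT2G23170) and GH3.5 (AT4G27260) rose at least 6.07-fold and 5.85-fold, with GH3.3 at the floor in wild type, and the regulators HAT2 (AT5G47370) and IAA29 (AT4G32280) rose 3.39-fold and 2.76-fold. With 4 genes called adjusted over the list alone and a mean of 1.51, the list gave a camera adjusted p = 0.00119 and adjusted p = 0.0412 with an estimated correlation, but its mean was 0.56 (adjusted p = 0.112) with all 7 wild type arrays as the control and 0.18 (adjusted p = 0.547) with those of the other experiments. Its genes were higher in WT_MYB29_MYB76 than in WT_ATR1_MYB51 by a mean of 1.16 (camera adjusted p = 0.0267). Of the aliphatic genes AT2G31790 rose 4.2-fold, GSTU20 2.77-fold and AT2G25450, at the floor in wild type, at least 2.07-fold. BCAT4 (log2 0.17) and AOP3 (log2 -0.26) were not called. The aliphatic list (3 adjusted over the list alone) had a mean of 0.90 and a camera adjusted p = 0.0111, but 0.121 as the adjusted p with an estimated correlation, 0.0799 without WT_ATR1_MYB51 replicate 2, and a mean of -0.49 with all 7 wild type arrays as the control. PYK10 fell 2.73-fold and the transporter GTR2 (AT5G62680) 3.61-fold, 2 of the 3 genes of breakdown and transport (2 adjusted over the list alone; mean -1.27; camera adjusted p = 0.0336, adjusted p = 0.0801 with an estimated correlation, and over the threshold without WT_ATR1_MYB51 replicate 1 or ATR1_OE replicate 1). MYC4 (log2 -1.24), the glutaredoxin GRX480 (log2 -2.64) and WRKY53 (log2 -1.83) also fell.

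MSRB5 rose most in ATR1_OE among named genes, from 22.4 ± 15.8 (SD, n = 2) to 2979 ± 945 (SD, n = 2), or 7.0 ± 0.54 (SE) on the log2 scale (limma adjusted p = 1.73e-06). BGLU28 rose by 6.48 ± 0.33 (SE), from 12.5 ± 4.99 (SD, n = 2) to 1636 ± 696 (SD, n = 2), AT3G28270 by 4.63 ± 0.77 (SE) and AT5G62280 by 4.41 ± 0.48 (SE). The deepest falls were those of AT5G55450 (log2 -4.45), AT2G43620 (log2 -3.92) and AT1G48100 (log2 -3.54). The metallothionein MT1C (AT1G07610) fell from 2488 ± 33.9 (SD, n = 2) to 250.3 ± 28.3 (SD, n = 2). No plastid-encoded probe set was called. limma called 2368 probe sets, 865 higher and 1503 lower, 1703 of them changed at least 2-fold. The median of all probe sets lay at -0.13 and at -0.01 after quantile normalization, which called 1025 higher and 1126 lower, so the surplus of lower calls depends in part on the scaling. Left-out arrays gave 793 (WT_ATR1_MYB51 replicate 2), 1072 (ATR1_OE replicate 2), 1292 (ATR1_OE replicate 1) and 1385 (WT_ATR1_MYB51 replicate 1), and PYK10, MYC4 and AT2G25450 lost their calls without any 1 of these 4. GSTU20, MGL and IAA29 lost theirs without any but the last, HAT2 and WRKY53 without WT_ATR1_MYB51 replicate 2, GRX480 without ATR1_OE replicate 2, CBL without ATR1_OE replicate 2 or WT_ATR1_MYB51 replicate 1, and AT5G55450 and AT2G43620 without either replicate 2.

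In MYB51_OE, compared with the same wild type arrays to ask the same for MYB51, fewer probe sets were called, and IGPS, UGT74B1, APS3 and SIR again rose. IGPS rose 7.12-fold to 5434 ± 553 (SD, n = 2) and UGT74B1 7.57-fold to 2442 ± 680 (SD, n = 2). APS3 rose 17.3-fold to 3743 ± 64.6 (SD, n = 2) and SIR 2.98-fold to 4315 ± 585 (SD, n = 2). The sulfate assimilation list (2 of 3 rose; adjusted over the list alone, 2 rose and 1 fell) had a mean of 1.70 and passed camera at adjusted p = 0.000407 and at adjusted p = 0.016 with an estimated correlation. AT2G31790 rose 4.14-fold, the 1 called gene of the aliphatic list (1 adjusted over the list alone). The other aliphatic genes were not called, with log2 differences of 0.66 for GSTU20, 0.32 for AOP3, 0.24 for BCAT4 and -0.35 for AT2G25450, the last at the floor in both groups. The list's mean of 0.59 gave a camera adjusted p = 0.0424, but 0.306 as the adjusted p with an estimated correlation, and adjusted p = 0.451, 0.0987 and 0.103 without WT_ATR1_MYB51 replicate 2, MYB51_OE replicate 1 and MYB51_OE replicate 2. It turned to -0.81 with all 7 wild type arrays as the control and to -1.36 with those of the other experiments. No methionine gene was called over all probe sets, 2 were adjusted over the list alone, and the list's mean of 0.71 gave a camera adjusted p = 0.014 (adjusted p = 0.0548 with an estimated correlation, 0.108 with all 7 wild type arrays as the control and 0.103 without MYB51_OE replicate 2). WRKY53 was lower by a log2 difference of -2.18.

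Among named genes in MYB51_OE, MSRB5 rose by 5.75 ± 0.54 (SE) to 1259 ± 440 (SD, n = 2; limma adjusted p = 2.23e-05), APS3 by 4.11 ± 0.34 (SE), BGLU28 by 3.80 ± 0.33 (SE) to 257.6 ± 120 (SD, n = 2), AT3G48410 by 3.48 ± 0.33 (SE) and AT3G23570 by 3.29 ± 0.38 (SE). AT2G43620 fell by 4.40, AT5G53710 by 2.97, and AT1G35710 and AT3G22060 by 2.93 each. An unnamed probe set, 255753_at, rose to 4711 ± 1951 (SD, n = 2) from 37.5 ± 23.5 (SD, n = 2). limma called 215 probe sets, 139 higher and 76 lower, 202 of them changed at least 2-fold, and 1720 had an unadjusted p under 0.05. The surplus of higher calls was absent with no filter (133 higher, 135 lower) and turned with the wild type arrays of the other experiments as the control (216 higher, 344 lower). The count was 90 without WT_ATR1_MYB51 replicate 2 and 103 without MYB51_OE replicate 2. AT2G31790, WRKY53 and AT2G43620 lost their calls without either of these arrays (AT2G43620 also without MYB51_OE replicate 1), and AT5G53710, AT1G35710 and AT3G22060 without the first.

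Directly compared, ATR1_OE and MYB51_OE differed in 417 probe sets by limma, 150 higher and 267 lower in ATR1_OE. Auxin response genes were higher in ATR1_OE: GH3.3 4.69-fold, GH3.5 4.27-fold and HAT2 2.82-fold. With 3 of 5 genes called (4 adjusted over the list alone) and a mean of 1.44, the list gave a camera adjusted p = 7.51e-05 and adjusted p = 0.0453 with an estimated correlation. AT2G25450 was at least 2.64-fold higher, the 1 called gene of the aliphatic list (1 adjusted over the list alone; mean 0.31; camera adjusted p = 0.315). AT1G12030 was higher in ATR1_OE by 4.98 ± 0.75 (SE) and AT4G01870 by 3.34 ± 0.56 (SE), and AT2G33850 and AT3G05600 were lower (log2 -3.18 and -3.14), as was the asparaginase ASPGB1 (log2 -2.56). The unnamed 255753_at was at least 344-fold lower in ATR1_OE, where it lay at the floor. The sulfate assimilation list did not differ past the threshold (mean 0.25, camera adjusted p = 0.342). The count was 64 without MYB51_OE replicate 1, 85 and 141 without ATR1_OE replicates 1 and 2, 713 without MYB51_OE replicate 2 and 11 in a model of this experiment alone, and the 3 auxin genes, AT4G01870, AT2G33850 and ASPGB1 lost their calls without ATR1_OE replicate 1 or MYB51_OE replicate 1 (GH3.5, HAT2 and ASPGB1 also without ATR1_OE replicate 2), AT1G12030 without ATR1_OE replicate 1, and AT2G25450 without any 1 of the 4 arrays. Against their shared wild type, 128 probe sets rose and 62 fell in both lines, where independent lists would share 7.7 and 7.3. That baseline does not allow for the shared wild type arrays, which by themselves make the changes of both lines alike. The changes correlated across probe sets with r = 0.659 (0.503 simulated) and a covariance of 0.266 (0.062 simulated), and with r = 0.4 and 0.374 when each line was set against another of the 2 wild type arrays.

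**Figure D2:**
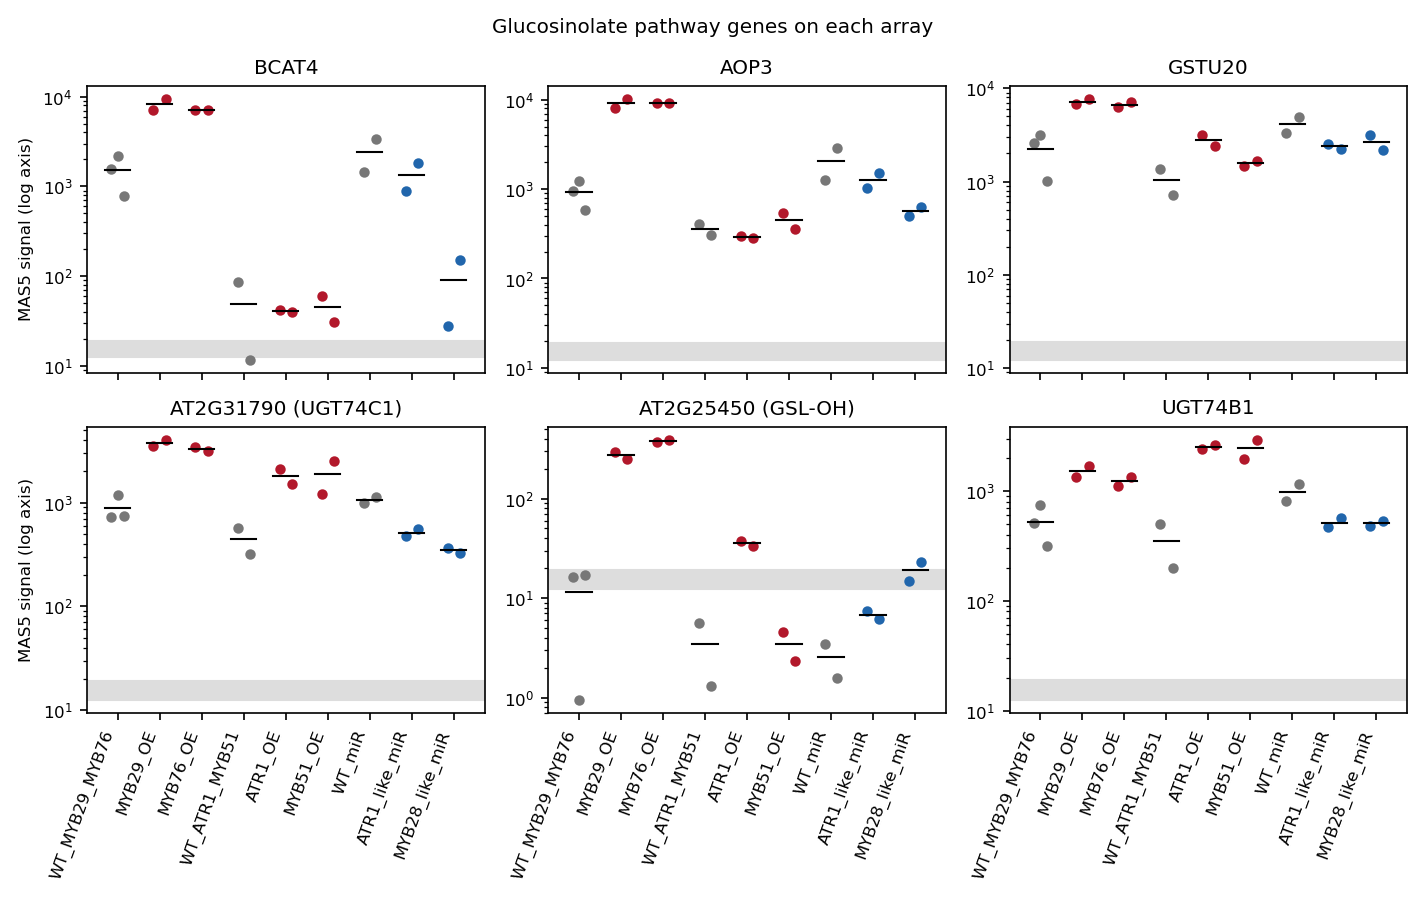
Signal of measured glucosinolate genes on each of the 19 arrays (dots, log axis) with the mean of each group (line) and the range of the floor (grey band). AT2G25450 reached 273.4 in MYB29_OE and 377.9 in MYB76_OE on average, and lay near the floor in the wild type groups.

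ATR1_like_miR was compared with WT_miR to ask which transcripts differ in seedlings with this artificial microRNA. Plastid-encoded transcripts rose: 54 of 68 probe sets were called higher, among them rpl22 by 7.17, petB by 7.14 and ndhI by 7.01 on the log2 scale. The median plastid-encoded signal was 10.3 ± 0.73 (SD, n = 2) on the log2 scale, against 5.05 ± 0.59 (SD, n = 2) in wild type. Of the other genes, the mitochondrial ccb382 rose by 3.82 ± 0.63 (SE), and AT2G07751 and AT2G07707 by 3.40 and 2.44. AT1G47400, which belongs to a family of peptides of iron homeostasis, fell 10.9-fold, from 345 ± 36.5 (SD, n = 2) to 32 ± 7.41 (SD, n = 2; limma adjusted p = 0.0119), AT3G48640 by 3.19 and AT2G32150 by 2.97. No gene of any list fixed earlier was called over all probe sets. The 5 aliphatic genes had a mean log2 difference of -0.69 (camera adjusted p = 0.302), 1 was lower adjusted over the list alone, and the log2 differences were -0.79 for BCAT4, -0.74 for GSTU20, -1.05 for AT2G31790 and -0.62 for AOP3, while AT2G25450, whose -0.27 enters the mean, lay at the floor on all 4 arrays. That mean turned to 0.24 with all 7 wild type arrays as the control and to 0.62 with those of the other experiments. It was -2.22 (camera adjusted p = 0.000715) with the plastid-encoded signal as a covariate. UGT74B1 (log2 -0.92), IGPS (log2 -0.31) and APS3 (log2 -0.74) were not called either. limma called 315 probe sets, 136 higher and 179 lower (184 and 142 with quantile normalization). Without the plastid-encoded probe sets the count was 211 (66 higher, 145 lower), and it was 135 with all 7 wild type arrays as the control, 2277 with those of the other experiments and 13 with the plastid-encoded signal as a covariate. Signal and group nearly coincide here, so the covariate takes up much of the contrast. With 1 array left out it lay between 74 (ATR1_like_miR replicate 2) and 166 (WT_miR replicate 2), and each of the 4 arrays moved it by over 1.5-fold. AT1G47400 lost its call without any 1 of these arrays, ccb382, AT2G07751 and AT2G07707 without WT_miR replicate 1 or ATR1_like_miR replicate 2 (AT2G07707 also without replicate 1), and the aliphatic list passed at adjusted p = 0.0234 without WT_miR replicate 1.

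MYB28_like_miR was compared with WT_miR to ask the same of the artificial microRNA named for MYB28, and 3 of 5 aliphatic glucosinolate genes fell. BCAT4 fell 34.1-fold, from 2408 ± 1383 (SD, n = 2) to 89.5 ± 87.5 (SD, n = 2), or by 5.09 ± 0.78 (SE) on the log2 scale (limma adjusted p = 0.00164). AOP3 fell 3.38-fold to 568.5 ± 94.4 (SD, n = 2) and AT2G31790 3.04-fold to 349.9 ± 27.8 (SD, n = 2). GSTU20 (log2 -0.61) and AT2G25450 (log2 at least 0.15, with both wild type arrays at the floor) were not called. The list had a mean of -1.78 and a camera adjusted p = 0.017 (0.426 as the adjusted p with an estimated correlation, 0.061 without WT_miR replicate 2, 0.0939 with no floor and 0.064 with the offset), with 3 genes called adjusted over the list alone. The mean was -0.84 (adjusted p = 0.788) with all 7 wild type arrays as the control and -0.47 (adjusted p = 0.866) with those of the other experiments. UGT74B1 (log2 -0.93), IGPS (log2 -0.24) and APS3 (log2 -0.69) were not called. The leaf polarity gene PHV was lower (log2 -1.17).

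Plastid-encoded transcripts were higher in MYB28_like_miR too: 51 of 68 probe sets rose, atpB by 7.29 and petB by 7.24, and the median signal was 9.80 ± 0.77 (SD, n = 2) on the log2 scale. AT4G12490, of a lipid transfer protein family, rose 24.4-fold, from 32.8 ± 3.54 (SD, n = 2) to 820.3 ± 262 (SD, n = 2), ccb382 rose by 3.40 and JRG21 by 2.84. AT1G60200 fell by 3.45, AT1G77030 by 3.09 and AT1G67870 by 2.85. limma called 1005 probe sets, 322 higher and 683 lower, and 728 changed at least 2-fold. The median of all probe sets lay at -0.14 and at -0.03 after quantile normalization, which called 363 higher and 362 lower. The count was 278 with all 7 wild type arrays as the control, 1952 (931 higher, 1021 lower) with those of the other experiments and 41 (19 higher, 22 lower) with the plastid-encoded signal as a covariate. Here too that signal nearly follows the groups, so the drop to 41 follows in large part from the setting. Left-out arrays gave 195 (WT_miR replicate 1), 299 (MYB28_like_miR replicate 2), 315 (WT_miR replicate 2) and 535 (MYB28_like_miR replicate 1). AT2G31790 lost its call without any 1 of these 4 arrays, AOP3 without either replicate 2, PHV and ccb382 without WT_miR replicate 1 or MYB28_like_miR replicate 2, and JRG21 and AT1G67870 without either replicate 1 (AT1G67870 also without WT_miR replicate 2).

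Between the artificial microRNA lines, limma called 5 probe sets, 1 higher and 4 lower in ATR1_like_miR, and 1214 had an unadjusted p under 0.05. AT1G77030 was 5.12-fold higher in ATR1_like_miR (103.7 ± 38.4 against 19.7 ± 3.46, SD, n = 2 each; limma adjusted p = 0.00652), a call lost without ATR1_like_miR replicate 1. The unnamed 254805_at, at the floor in ATR1_like_miR, was at least 19.1-fold lower and 259553_x_at 5.91-fold lower, calls lost without any array but MYB28_like_miR replicate 1. BCAT4 differed by 4.3 ± 0.78 (SE) with a limma adjusted p = 0.0646 and was not called. The aliphatic list had a mean difference of 1.09 (camera adjusted p = 0.0977, but 0.0328 with quantile normalization and 0.0384 with no filter), and 2 genes were called adjusted over the list alone. Against their shared wild type 63 probe sets rose and 116 fell in both lines, plastid-encoded ones left out, where independent lists would share 1.4 and 7.9. That baseline does not allow for the shared wild type arrays, which by themselves make the changes of both lines alike. The changes correlated across probe sets with r = 0.749 (0.5 simulated) and a covariance of 0.249 (0.062 simulated), and with r = 0.469 and 0.464 when each line was set against another of the 2 wild type arrays.

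Over the 4 overexpressing lines, 54 probe sets rose in all 4 and 14 fell in all 4, where independent lists would give 0.0446 and 0.0272. Of those that rose, 19 were assigned to 1 gene, and they included BGLU28, MSRB5, APS3, UGT74B1 and AT2G31790. TAAC (AT5G01500), a carrier of ADP, ATP and the sulfate donor PAPS, rose by 2.81, 2.49, 2.89 and 2.86 on the log2 scale in MYB29_OE, MYB76_OE, ATR1_OE and MYB51_OE, and AT3G48410 by 2.32, 2.57, 3.80 and 3.48. In the same order MT1C fell by 1.60, 1.09, 3.32 and 2.38, and AT5G03350 by 3.21, 2.76, 2.35 and 2.70. AT3G48640 fell in all 6 lines, by 1.95 in ATR1_OE to 3.19 in ATR1_like_miR. The lines of an experiment share wild type arrays, so these counts are not independent. No gene of the auxin biosynthesis (3 measured) or flavonoid (4 measured) lists was called in any of the 9 comparisons, where the lowest camera adjusted p of these lists was 0.477 and 0.134.

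**Figure D3:**
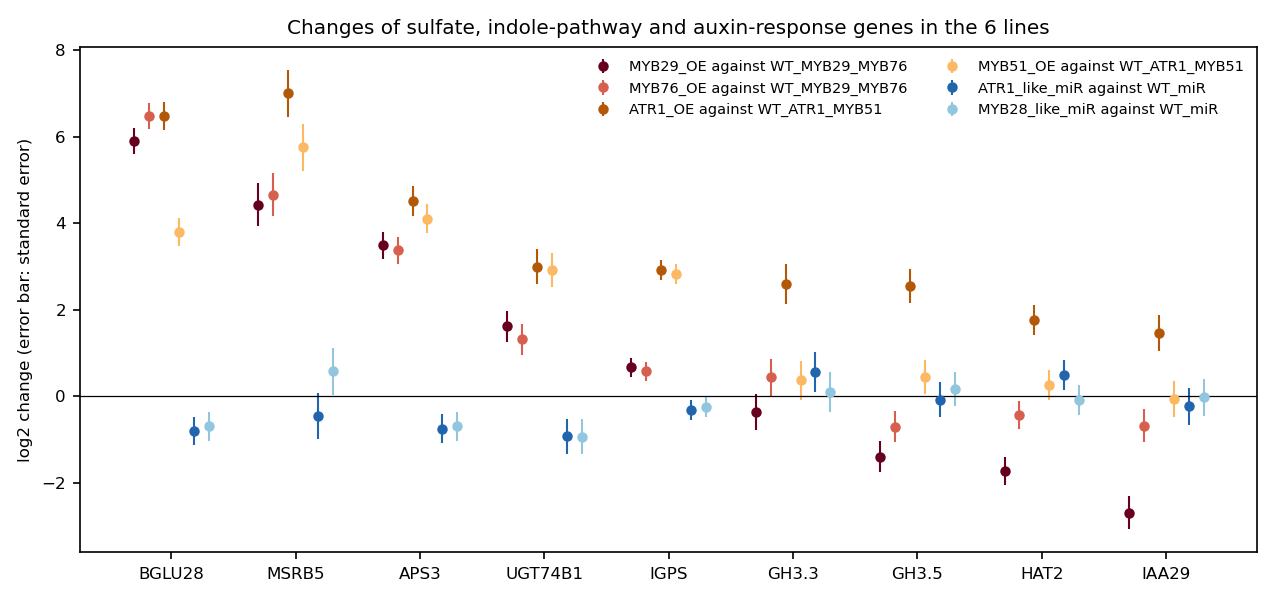
Log2 change against wild type (points, bars ± SE from limma) of 9 genes in the 6 lines. BGLU28 and MSRB5 rose in all 4 overexpressing lines, by 3.80 to 6.48 and by 4.43 to 7.0, while GH3.3 and HAT2 rose in ATR1_OE.

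Wild type arrays of the 3 experiments differed among themselves. limma's F-test called 3835 of the tested probe sets (24.5%), and 1045 differed between WT_MYB29_MYB76 and WT_ATR1_MYB51, 3306 between WT_MYB29_MYB76 and WT_miR, and 2037 between WT_ATR1_MYB51 and WT_miR. BCAT4 had a signal of 48.9 ± 52.6 (SD, n = 2) in WT_ATR1_MYB51, against 1510 ± 694 (SD, n = 3) in WT_MYB29_MYB76 (limma adjusted p = 0.000519) and 2408 ± 1383 (SD, n = 2) in WT_miR (limma adjusted p = 0.000226). AOP3 had 355.8 ± 66.9 (SD, n = 2), 918.9 ± 318 (SD, n = 3) and 2074 ± 1142 (SD, n = 2) in the same order. Plastid-encoded medians were 5.91 ± 0.67 (SD, n = 2), 9.73 ± 1.64 (SD, n = 3) and 5.05 ± 0.59 (SD, n = 2) on the log2 scale.

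**Figure D4:**
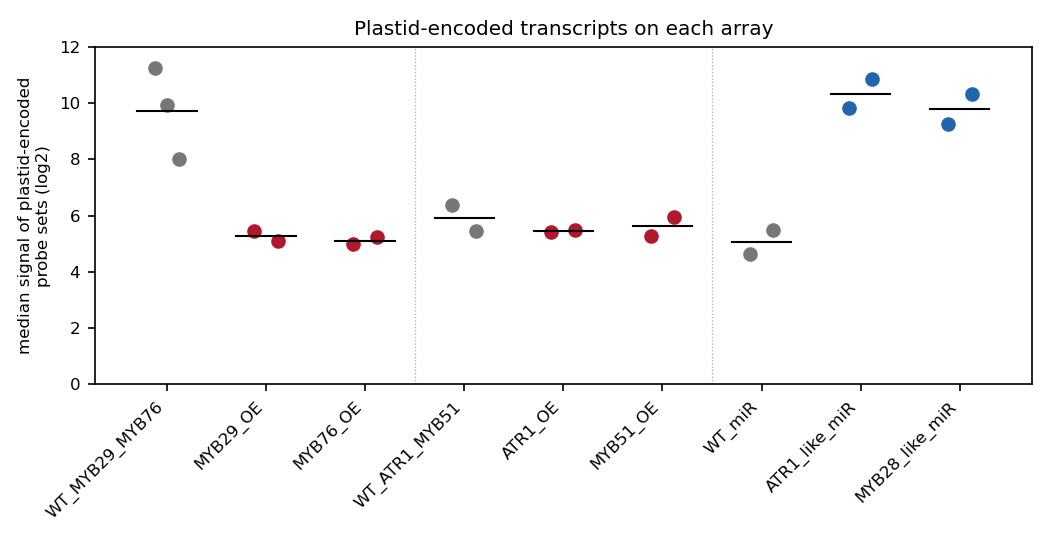
Median log2 signal of 69 plastid-encoded probe sets on each array (dots) with the mean of each group (line). Arrays of WT_MYB29_MYB76 and both artificial microRNA lines lie above the others, up to 11.3, and the lowest array lies at 4.64.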

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

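All tests of this part were chosen after the result was seen, except the comparisons between lines and the share of changed probe sets that kept their direction against the other wild type groups.

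The auxin response list drew attention because lines set against the same wild type arrays differed when they were compared directly, by a mean log2 difference of -0.87 for MYB29_OE against MYB76_OE and of 1.44 for ATR1_OE against MYB51_OE. For the same reason the glucosinolate breakdown and transport list stands here, with -0.76 for MYB29_OE against MYB76_OE. All 3 differences passed camera's test with the preset and with the estimated correlation, but the last missed it without MYB29_OE replicate 2 (mean -0.43).

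A control probe set of the array, AFFX-r2-At-U12639_at, stands here because it lies outside the tested probe sets and was bright in 2 groups alone. Its mean signal was 100.2-fold that of wild type in ATR1_OE (3346 and 3775 on the 2 arrays) and 51.02-fold in MYB51_OE (952.7 and 2674), while the other 15 arrays lay between 8.26 and 37.2. The other 63 control probe sets had a median ratio of 0.92 in MYB51_OE, and what the probe set measures is not given in the tables.

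Plastid-encoded probe sets were lower in MYB29_OE and MYB76_OE and higher in both artificial microRNA lines than in their own wild type arrays, with list means of -4.26, -4.32, 4.84 and 4.35 (camera adjusted p = 6.32e-55, 1.74e-56, 9.22e-107 and 1.32e-72; with an estimated correlation adjusted p = 0.0939, 0.087, 0.0236 and 0.0838). The introduced genes as the only cause are argued against by the wild type arrays, which carry none and whose medians differed by 4.68 ± 0.79 (SE) on the log2 scale between WT_MYB29_MYB76 and WT_miR. More or less green tissue is argued against by the nuclear photosynthesis list, which showed at most 7.5% of the plastid-encoded change (means of -0.32, -0.24, 0.08 and 0.30). For a labelling batch that takes up RNA without a long poly(A) tail the values go both ways: all 9 mitochondrion-encoded probe sets measured moved the same way as the plastid-encoded ones in all 4 comparisons (medians of -1.54, -1.11, 1.48 and 0.97, with 5, 3, 3 and 3 called), but the 25S rRNA control probe set, also without such a tail, was bright in WT_MYB29_MYB76 alone (2294 ± 3716, SD, n = 3, with 6582 on 1 array) and had group means of 2.72 to 11.1 elsewhere, the artificial microRNA lines included. Such a batch and a change of organelle transcripts in the plants cannot be told apart, since no label gives a batch, and exchanged wild type labels, weighed next, stay open here too.

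Of the 1345 probe sets that changed the same way in MYB29_OE and MYB76_OE, which may reflect the introduced factors, wild type arrays that stand apart or both, 104 (81 higher, 23 lower) were called in the same direction in both lines against all 3 wild type groups, among them BGLU28, MSRB5, APS3, CBL and MT1C. Against each of the other wild type groups 55.8% of the 1345 (751) kept their direction in both lines. Of all tested probe sets 39.7% have 1 direction in all 4 such comparisons. That share counts either direction, so it overstates how often a given direction would be kept and is no like baseline for the 55.8%. Most of the 1345 were not called against all 3 wild type groups, and for these the wild type arrays and the lines cannot be told apart. In the aliphatic list 3 of 5 genes (AOP3, AT2G31790 and AT2G25450) were also called higher in both lines against both other wild type groups, while BCAT4 and GSTU20 were not against WT_miR. All 5 had higher means there, the least by 0.74 on the log2 scale (GSTU20 in MYB76_OE against WT_miR). For the 3 genes these values argue against wild type arrays that stand apart as the only cause. For BCAT4 and GSTU20 the explanations cannot be told apart. Exchanged and correct labels of WT_MYB29_MYB76 and WT_miR cannot be told apart either: after an exchange the plastid-encoded medians of 9.73 and 5.05 would lie beside those of their lines (10.3 and 9.80, and 5.26 and 5.11), and calls other than plastid-encoded ones would fall from 2243 to 843 in MYB29_OE and from 1940 to 1071 in MYB76_OE. On the other side the median size of change would grow 1.32-fold in ATR1_like_miR (0.82, 0.87 and 1.04 in MYB29_OE, MYB76_OE and MYB28_like_miR), and such calls from 261 to 2430 (1263 to 3438 with 1 wild type array left out) there and from 954 to 1752 (692 to 3105) in MYB28_like_miR, which an effect of the microRNAs could also give.

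Of the probe sets higher in MYB29_OE and MYB76_OE, 111 were lower in MYB28_like_miR, which would suit genes under control of this group of factors. In ATR1_like_miR, however, the same set had a median log2 change of -0.74 (110 of 111 below 0), and since a negative value there also follows from sharing the wild type arrays, the set was chosen again with 1 WT_miR array and measured against the other: the medians were -1.06 (30 probe sets, chosen with replicate 1) and -0.62 (41, with replicate 2), against -0.11 and -0.08 over all tested probe sets. An array difference of the kind that the plastid-encoded signal shows may therefore account for part of the set, since both artificial microRNA lines and WT_MYB29_MYB76 share it, while an effect common to both microRNAs stays open as well. Only 1 member was called between the artificial microRNA lines, and 12 were among the 104 above. For the member BCAT4 an effect of that microRNA stays open, with a difference of 4.3 ± 0.78 (SE) between the lines (limma adjusted p = 0.0646).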

How the results depend on the processing

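Chosen only after the results were seen were the omission of plastid-encoded probe sets, the wild type arrays of the other 2 experiments as the control, the plastid-encoded median as a covariate, the crossed replicate block and the wild type arrays split between lines. None of them was run for the gene and comparison pairs counted next, and some of the fixed alternatives covered only part of these pairs. Of 196 gene and comparison pairs followed, 65 kept direction and side of the threshold under every alternative run and 131 changed under at least 1. The mean of the aliphatic list in MYB29_OE and MYB76_OE kept its direction and camera call under every alternative run for it, though calls of its genes BCAT4 and GSTU20 did not hold, and the 3835 probe sets differing among wild type arrays became 3869 with quantile normalization and 3391 without the filter. Signal over background limits AT2G25450, IAA29 and GH3.3, which lay at the floor in some groups. The list of indole glucosinolate synthesis was not run, since 0 of its genes were named. Where no cause follows from the setting itself (fewer arrays or probe sets, merged wild type groups, or a covariate that nearly follows the contrast), the cause was not tested.

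Between the artificial microRNA lines the aliphatic list passed with quantile normalization (1.11, adjusted p = 0.0328) and with no filter (1.09, adjusted p = 0.0384). Quantile normalization gave 0.00 for AT2G25450 in MYB51_OE and -0.01 for the aliphatic list in MYB29_OE against MYB76_OE. With no floor AT2G25450 was 0.26 in MYB51_OE and 1.51 in ATR1_like_miR, the aliphatic list in MYB28_like_miR was -1.22 (adjusted p = 0.0939) and 1 probe set was called between the artificial microRNA lines. As an offset, the percentile gave 0.09 for AT2G25450 in ATR1_like_miR and -1.57 for the aliphatic list in MYB28_like_miR (adjusted p = 0.064). With no filter 9 probe sets were called in MYB29_OE against MYB76_OE, 261 in ATR1_OE against MYB51_OE and 10 between the artificial microRNA lines, where the stricter filter gave 2. In models of 1 experiment 1456 were called in MYB29_OE, 1286 in MYB76_OE, 1108 in ATR1_OE, 97 in MYB51_OE, 11 in ATR1_OE against MYB51_OE and 15 between the artificial microRNA lines. Without the trend the aliphatic list in MYB51_OE stayed at 0.59 (adjusted p = 0.0781) and 9 probe sets were called in MYB29_OE against MYB76_OE. A threshold of 2-fold as well left 1279 in MYB29_OE and 1146 in MYB76_OE. With the estimated correlation the aliphatic list lost its call in ATR1_OE (0.90), MYB51_OE (0.59) and MYB28_like_miR (-1.78), at adjusted p = 0.121, 0.306 and 0.426.

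With all 7 wild type arrays as the control 217 probe sets were called in MYB29_OE, 253 in MYB76_OE, 135 in ATR1_like_miR and 278 in MYB28_like_miR. The aliphatic list then was -0.49 in ATR1_OE, -0.81 in MYB51_OE, 0.24 in ATR1_like_miR and -0.84 in MYB28_like_miR, nuclear photosynthesis in MYB28_like_miR -0.18 and the auxin response in ATR1_OE 0.56 (adjusted p = 0.112). BCAT4 became -3.78 in ATR1_OE, -3.71 in MYB51_OE and 1.18 in ATR1_like_miR, GSTU20 -0.35 in MYB51_OE, 0.26 in ATR1_like_miR and 0.39 in MYB28_like_miR, and AOP3 -0.94 in MYB51_OE and 0.56 in ATR1_like_miR. With the wild type arrays of the other 2 experiments 236 were called in MYB29_OE, 283 in MYB76_OE, 560 in MYB51_OE, 2277 in ATR1_like_miR and 1952 in MYB28_like_miR. Merged wild type groups carry the differences between experiments in their spread, so calls can be lost for that reason. Against WT_ATR1_MYB51 and WT_miR apart, 661 and 843 probe sets were called in MYB29_OE and 757 and 1071 in MYB76_OE. With the merged arrays of the other 2 experiments the aliphatic list was -1.05 in ATR1_OE, -1.36 in MYB51_OE, 0.62 in ATR1_like_miR and -0.47 in MYB28_like_miR, nuclear photosynthesis 0.01 in MYB29_OE, 0.08 in MYB76_OE and -0.37 in MYB28_like_miR (a call in the opposite direction, camera adjusted p = 0.000113), the auxin response in ATR1_OE 0.18 (adjusted p = 0.547) and the methionine list in ATR1_OE 0.75 (adjusted p = 0.0644). Plastid-encoded genes lost their call with these arrays in MYB29_OE (-0.28) and MYB76_OE (-0.35), and kept it in ATR1_like_miR (1.92) and MYB28_like_miR (1.43). With the plastid-encoded median as a covariate 209, 218, 13 and 41 were called in MYB29_OE, MYB76_OE, ATR1_like_miR and MYB28_like_miR, the aliphatic list was -2.22 in ATR1_like_miR (adjusted p = 0.000715) and -0.05 in MYB29_OE against MYB76_OE, and in MYB29_OE the auxin response was -0.48 and the breakdown and transport list -0.25 (adjusted p = 0.323 and 0.77). In these 4 lines the covariate nearly follows the split between line and wild type, so this fit cannot tell an effect of the line from one tied to that signal. In ATR1_OE, whose median of 5.45 lay near the 5.91 of its wild type, 2320 were called.

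Same-numbered arrays did not deviate together (correlations from -0.22 to 0.16), so the numbers do not pair them. The value of -0.22 was that between the artificial microRNA lines, where a pairing across the numbers was not excluded. With the replicate number as a block 1243 probe sets were called in MYB29_OE and 1013 in MYB76_OE, and no other count moved by over 1.5-fold. The breakdown and transport list in ATR1_OE (mean -1.27) and nuclear photosynthesis in MYB76_OE (mean -0.2) then missed the threshold (camera adjusted p = 0.0532 and 0.0622). With crossed numbers in the block 11 were called between the artificial microRNA lines and 1017 in MYB28_like_miR.

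With 1 array left out, where a lone array is assumed to vary like the other groups, the counts ranged from 288 (MYB29_OE replicate 2) to 2865 in MYB29_OE, from 386 (MYB76_OE replicate 1) to 2658 in MYB76_OE, from 793 to 1385 in ATR1_OE, from 90 to 249 in MYB51_OE, from 74 to 166 in ATR1_like_miR and from 195 to 535 in MYB28_like_miR. Direct comparisons ranged from 1 to 21 (MYB29_OE replicate 1), from 64 to 713 and from 1 to 24 (MYB28_like_miR replicate 1). The aliphatic list ranged from 0.40 (WT_ATR1_MYB51 replicate 2) to 1.40 in ATR1_OE, from 0.09 (the same array) to 1.08 in MYB51_OE, from -1.03 (WT_miR replicate 1) to -0.36 in ATR1_like_miR, from -2.12 to -1.44 (WT_miR replicate 2) in MYB28_like_miR and from -0.09 to 0.09 in MYB29_OE against MYB76_OE. BCAT4 ranged from -1.08 to 1.42 in ATR1_OE and from -1.01 to 1.49 in MYB51_OE, and AT2G25450 from -0.16 to 0.47 in MYB28_like_miR.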

Other observations

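The lists of this part were added after the annotation had been seen, so their tests were chosen later than the design.

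Chaperones of the heat shock response rose in MYB29_OE and MYB76_OE. Of 12 measured genes 6 rose in MYB29_OE and 8 in MYB76_OE, with mean log2 changes of 1.49 and 1.67 (camera adjusted p = 5.01e-06 and 3.01e-07; with an estimated correlation adjusted p = 0.0309 and 0.0156). The small heat shock protein gene AT2G29500, at the floor in wild type, rose at least 16.7-fold and at least 20.9-fold, AT1G53540 rose 7.54-fold and 8.22-fold, and the co-chaperone Fes1A 3.02-fold and 4.09-fold. AT2G29500, AT1G53540, AT5G37670 and Fes1A were also higher in both lines against the wild type arrays of the other experiments, no heat shock gene rose in the other lines, and Hsp70-2 fell in ATR1_OE (log2 -1.41). Genes of the ER body, a compartment of defence-related beta-glucosidases, were lower in MYB29_OE, where 4 of 7 fell (mean -1.35; camera adjusted p = 8.91e-05, and adjusted p = 0.124 with an estimated correlation): JAL22 5.86-fold, JAL34 4.12-fold, PYK10 3.78-fold and JAL33 3.01-fold. Compared directly with MYB76_OE the mean was -1.02 (camera adjusted p = 5.7e-11; adjusted p = 0.0234 with an estimated correlation), but no single gene of the list was called (lowest limma adjusted p = 0.6). Against wild type JAL22 fell in MYB76_OE as well (log2 -2.07). In ATR1_OE PYK10, NAI2 and JAL33 fell (log2 -1.45, -1.30 and -0.93), while JAL23, at the floor in wild type, rose by at least 1.85. The cold response list (4 measured) differed between MYB29_OE and MYB76_OE by -2.25 (camera adjusted p = 1.1e-05; adjusted p = 0.136 with an estimated correlation), with COR47 lower in MYB29_OE (log2 -1.30) and LTI30 higher in MYB76_OE (log2 3.59) against wild type. No gene of the list was called between these lines, where COR15A, COR15B and LTI30 had standard errors of 1.49, 1.08 and 1.07. LTI30 was also higher in MYB28_like_miR than in WT_miR, by 3.72, just short of a call (limma adjusted p = 0.0501). Sugar transporters of the SWEET family were lower in both lines, 2 of 10 in MYB29_OE and 4 of 10 in MYB76_OE (means -0.87 and -0.84; camera adjusted p = 0.00448 and 0.00806; with an estimated correlation adjusted p = 0.192 and 0.327), and SWEET11 fell by 2.39 and 2.23 on the log2 scale. With all 7 wild type arrays as the control the SWEET means were -0.52 and -0.49 (adjusted p = 0.0743 and 0.0897), and with those of the other experiments -0.25 and -0.22 (adjusted p = 0.444 and 0.451).

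Genes of cell division were lower in ATR1_OE, where 11 of 16 fell (mean -1.37; camera adjusted p = 2.73e-06, and adjusted p = 0.623 with an estimated correlation). KINESIN-12B fell 3.89-fold, the Aurora kinase AUR2 3.82-fold and the centromeric histone HTR12 3.81-fold. Directly against MYB51_OE 3 of 16 were lower (mean -1.13; camera adjusted p = 3.43e-08, and adjusted p = 0.409 with an estimated correlation), KINESIN-12B, HTR12 and AUR1. AUR1 and AUR2 rose in MYB29_OE (log2 1.40 and 1.35) and in MYB76_OE (log2 1.09 and 1.19). Wild type arrays differed in this list too, by -1.25 for WT_MYB29_MYB76 and -1.14 for WT_ATR1_MYB51 against WT_miR (camera adjusted p = 6.09e-05 and 2e-05). In the same order the ER body list differed by -1.50 and -2.16 (camera adjusted p = 0.00083 and 1.37e-06), the SWEET family by 0.97 and 0.69 (0.0059 and 0.0334) and nuclear photosynthesis by 0.66 and 0.67 (4.18e-11 and 6.51e-11), and the touch and wounding list by 0.71 for WT_ATR1_MYB51 against WT_miR (0.00852). The touch and wounding list had means of -0.73 in MYB29_OE and -0.81 in MYB51_OE (1 of 10 called in each, PUB23 and WRKY53; camera adjusted p = 0.0108 and 0.00372; with an estimated correlation adjusted p = 0.294 and 0.656), which became -0.29 and -0.50 (adjusted p = 0.412 and 0.322) with a filter at the 60th percentile, and in MYB51_OE -0.40 (adjusted p = 0.249) with all 7 wild type arrays as the control and -0.23 (adjusted p = 0.694) with those of the other experiments. The nuclear photosynthesis list (16 measured) differed by small means, with camera adjusted p = 0.00113 in MYB29_OE (mean -0.32), 0.0107 in MYB76_OE (-0.24), 0.000805 in ATR1_OE (0.34), 1.52e-05 in MYB28_like_miR (0.30), 3.43e-08 in ATR1_OE against MYB51_OE (0.42) and 2.35e-05 between the artificial microRNA lines (-0.22). None of these passed with an estimated correlation (adjusted p from 0.174 to 0.623) or with quantile normalization, which gave -0.21, -0.13, 0.16, 0.04, 0.17 and -0.05. In MYB28_like_miR the mean turned to -0.18 (camera adjusted p = 0.451) with all 7 wild type arrays as the control. With those of the other experiments it was -0.37 (camera adjusted p = 0.000113) there, 0.01 in MYB29_OE and 0.08 in MYB76_OE.

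Of the 11 gene families, 7 passed no test in the 9 comparisons. In MYB29_OE the CYP71B family had a mean of -0.58 (camera adjusted p = 0.0296) and the calmodulin-like CML family of -0.95 (camera adjusted p = 0.0392), and between the artificial microRNA lines expansins differed by -0.46 (camera adjusted p = 0.00141) and CYP71B by -0.39 (camera adjusted p = 0.0123), none past the threshold with an estimated correlation (adjusted p = 0.182, 0.164, 0.174 and 0.174). In MYB29_OE both families missed the threshold also with all 7 wild type arrays as the control (means of -0.37 and -0.60; adjusted p = 0.087 and 0.145) and with those of the other experiments (-0.21 and -0.33; adjusted p = 0.548 and 0.683), CYP71B also with the 60th percentile filter (-0.27; adjusted p = 0.37), and CML with quantile normalization, no floor and the offset (adjusted p = 0.0582, 0.102 and 0.0602). Plastid-encoded genes differed by 0.49 between the artificial microRNA lines (camera adjusted p = 0.0486, but 0.78 as the adjusted p with an estimated correlation, 0.0851 with no floor, 0.0817 with the 60th percentile filter, 0.0683 without the trend and 0.562, at a mean of 0.04, with the plastid-encoded signal as a covariate). Mean log2 signals of MYB29_OE correlated across probe sets with r = 0.911 with its own wild type group, 0.932 with WT_ATR1_MYB51 and 0.935 with WT_miR, and for MYB76_OE the values were 0.911, 0.928 and 0.93. ATR1_like_miR correlated with r = 0.934 with its own WT_miR and 0.925 with WT_MYB29_MYB76, and MYB28_like_miR with 0.923 and 0.933.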
